A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

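The series holds 24 arrays that each compared total RNA of 2 yeast strains in 2 dyes. Per the labels, dot4-1 (UCC6406) and dot4-5 (UCC6407) carry alleles of DOT4 with a 6Myc tag, UCC6435 is a dot4 null strain, and UCC6432 carries DOT4 without the tag. Each of these 4 strains was set against UCC6408, which carries DOT4-6Myc, after growth in YEPD, a rich glucose medium. Each strain has 3 numbered sets, and each set has 2 arrays on which the dyes were exchanged, so that each strain has 6 arrays. DOT4 is the gene named UBP10 in the reference annotation (YNL186W), which encodes a deubiquitinase of histone H2B. What dot4-1 and dot4-5 change in the protein, and the other markers of the strains, are not given in the sources used here.

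The table gives 1 value per array for 6205 open reading frames, with 83 of 148920 cells empty. The deposited values are log2 ratios of the 2 channels. The labels state no scale, and it was settled from the values: log2 of 2.5, 3, 4 and 5 filled 11, 19, 8 and 4 cells, against means of 1.2, 0.3, 0.15 and 0.05 cells at neighbouring values. Array type, scanner, background subtraction and normalization are not given in the sources used here. The deposited arrays were not centred. With the compared strain in Cy5, the medians of sets 1, 2 and 3 were -0.092, 0.029 and 0.087 for dot4-1, -0.051, 0.093 and -0.001 for dot4-5, 0, -0.046 and 0.1355 for the strain labelled null, and 0.021, 0.2755 and 0.246 for untagged DOT4. With the compared strain in Cy3, they were 0.054, 0.067 and -0.011 for dot4-1, 0.081, 0.009 and 0.037 for dot4-5, 0.065, 0.149 and -0.005 for the strain labelled null, and -0.086, 0.1775 and -0.02 for untagged DOT4. The number of arrays limits the precision of every value.

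The direction of the ratios is not stated beyond the order of strains and dyes in the labels. Read in that order, as Cy5 over Cy3, UBP10 was higher in the strain labelled null on 6 of 6 arrays. The mean of the 2 dye orientations as deposited keeps the dye effect, the dye component, while the strain effect cancels. This component correlated across genes at 0.822 to 0.906 between all pairs of strains. The dye in the numerator was thus the same on arrays of all 4 strains. All 24 arrays were therefore turned, which departs from the planned rule of following the labels. All signs are given in this likely direction, the compared strain over DOT4-6Myc. Under the order in the labels every sign is exchanged and the number of genes in each comparison stays the same. An exchange of strain names on the null arrays only would instead change the differences between the strain labelled null and the other strains.

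Each array was centred on its median and turned, and the 2 arrays of a set were averaged, so that a dye effect cancels. The 12 set means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a mean for each strain, no covariate and 8 residual degrees of freedom. A gene was tested where at least 2 of 3 sets of every strain had a value in both orientations, which left 6195 genes and removed 10. The tests were two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. There were 8 comparisons: 4 of a strain with DOT4-6Myc and 4 of strains with each other through that shared reference. Whether the sets are separate cultures, and whether the reference RNA was 1 batch, are not given in the sources used here. The p-values therefore measure the spread between sets, which may be technical in part. That spread is pooled over the 4 strains for each gene, so a p need not follow the SD of 1 strain. ADH4 in dot4-1, for example, had an SD of 0.014 but a standard error of 0.20 in the fit.

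Before the data were examined, 36 gene lists were fixed. Of these, 35 had at least 3 measured members and were tested with camera at a preset correlation of 0.01 between genes, on the 6176 genes with all set means, adjusted over the 280 tests of lists and comparisons. The same test with an estimated correlation, and fry, were run beside it. Genes near chromosome ends were taken as the 10 outermost protein-coding genes at each end of the 16 nuclear chromosomes, and called genes were counted inside and outside with two-sided Fisher's exact tests. Of the IDs in the table, 5705 matched the reference annotation and 500 keep the ID of the table. Correlations across genes have no p, because genes are not independent replicates.

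The genes named were chosen by a rule set before the data were examined. They are UBP10 and the genes on either side of it, the 10 largest rises and falls past the threshold with 1 sign in all 3 sets for each strain against DOT4-6Myc, the 5 largest each way for each difference of strains, and up to 4 members with the largest change in a list. Genes named outside this rule are said to be so. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

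The fit was tested on simulated data with known changes in 6176 genes. For a strain against DOT4-6Myc it recovered 83.6% of 67 changes of 0.3, 98.5% of 67 changes of 0.6 and 100% of 66 changes of 1, with 11 false calls. For a difference of 2 strains it recovered 76.1%, 94.0% and 100%, with 18 false calls. In these simulations few genes changed, in 1 strain only, and the noise was independent between all set means. The data share a reference and have many more called genes, so the rates describe that simpler setting. Alternatives tried were values without centring, arrays scaled to a common median absolute deviation, separate arrays with a dye effect, a single dye orientation, other filters on missing values, the set number as a replicate block, a fit of only the strains compared, robust eBayes, and leaving out each set. Set numbers were also checked as pairs: the residuals of dot4-1 and null sets with the same number correlated across genes at 0.672, 0.509 and 0.317, and over the 18 same-number pairs of all strains the median was 0.0174. Residuals of the 2 dye orientations of a set correlated at 0.370 to 0.778 in dot4-1 and the strain labelled null. In untagged DOT4 these were 0.593, 0.158 and 0.476. In dot4-5 they were -0.067, -0.136 and -0.133, so its sets showed no signal of their own that both orientations shared.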

Results

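The arrays measured transcript ratios of 6205 open reading frames in 4 strains, each with 6 arrays in 3 sets, against a strain with DOT4-6Myc. All values below are log2 ratios, with the SD over the 3 sets where ± is given.

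The comparison of the strain labelled null with DOT4-6Myc asks which transcripts differ without DOT4. UBP10 (YNL186W), the gene itself, was 25.8-fold lower at -4.69 ± 0.37 (SD, n = 3 sets, adjusted p = 1.22e-11). The likely direction rests on this gene, because in the order of the labels UBP10 would be higher in the strain labelled null on 6 of 6 arrays and every sign in the text would be exchanged. The largest rises were RRN3 (YKL125W), an initiation factor of RNA polymerase I, at 1.14 ± 0.051, and ADH4 (YGL256W), an alcohol dehydrogenase gene near the left end of chromosome VII, at 1.07 ± 0.30. Next, at 0.99 to 1.04, came YRF1-7, YRF1-3, YRF1-4 and YRF1-6, genes of the Y' helicases that lie at chromosome ends. YLL066C and YML133C, also at chromosome ends, and BPH1 and CHA1 rose within the same range. The largest falls after UBP10 were YNL134C at -2.55 ± 0.41, the glutathione transferase GTT2 (YLL060C) at -2.48 ± 0.32, the phosphate transporter PHO89 (YBR296C) at -2.19 ± 0.46 and the histidine synthesis gene HIS3 (YOR202W) at -1.72 ± 0.21. APE1, YML131W and 3 open reading frames of Ty elements, YML040W, YMR051C and YJR028W, also fell, to between -1.66 and -1.56.

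In the strain labelled null, all 7 Y' helicase genes rose (7 adjusted over the list alone, median 1.00), led by YRF1-7 at 1.04 ± 0.17 and YRF1-3 at 1.02 ± 0.16. Among the 29 PAU genes, which encode seripauperins and lie mostly near chromosome ends, 21 rose and 5 fell (22 and 5 adjusted over the list alone, median 0.65), with PAU3 at 0.90 ± 0.019 and PAU5 at 0.88 ± 0.077. Ribosome biogenesis genes rose in 67 of 70 cases and 0 fell (67 adjusted over the list alone, median 0.51), with MAK16 at 0.85 ± 0.18 and UTP9 at 0.85 ± 0.079. Genes induced in the environmental stress response fell in 27 of 37 cases and 4 rose (28 and 4 adjusted over the list alone, median -0.44), with PGM2 at -1.14 ± 0.17 and GPH1 at -1.06 ± 0.17. Glycolysis genes fell in 16 of 17 cases (16 adjusted over the list alone), with TDH1 at -0.85 ± 0.23 and PGK1 at -0.80 ± 0.25. Phosphate regulon genes fell in 13 of 18 cases and 1 rose (13 and 1 adjusted over the list alone), with PHO8 at -1.10 ± 0.11. Respiration and TCA cycle genes fell in 34 of 46 cases and 1 rose (36 and 1 adjusted over the list alone), with CIT1 at -0.72 ± 0.21. The camera test gave adjusted p = 6.42e-06 for the Y' helicases, 2.17e-06 for the PAU genes, 2.20e-17 for ribosome biogenesis, 7.36e-06 for the stress genes, 1.22e-05 for glycolysis, 9.04e-05 for the phosphate regulon and 1.65e-05 for respiration. For these lists adjusted p = 0.558 to 0.767 with an estimated correlation, so these list calls do not hold with it.

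In all, 3928 of 6195 genes passed in the strain labelled null, 1904 higher and 2024 lower, and 57 of them changed by at least 2-fold. Among common strain markers HIS3 and LEU2 fell, LEU2 to -0.93 ± 0.16, while ADE2 rose by 0.93 ± 0.14 and URA3 by 0.60 ± 0.22, and the marker genotypes of the strains are not given in the sources used here.

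**Figure D1:**
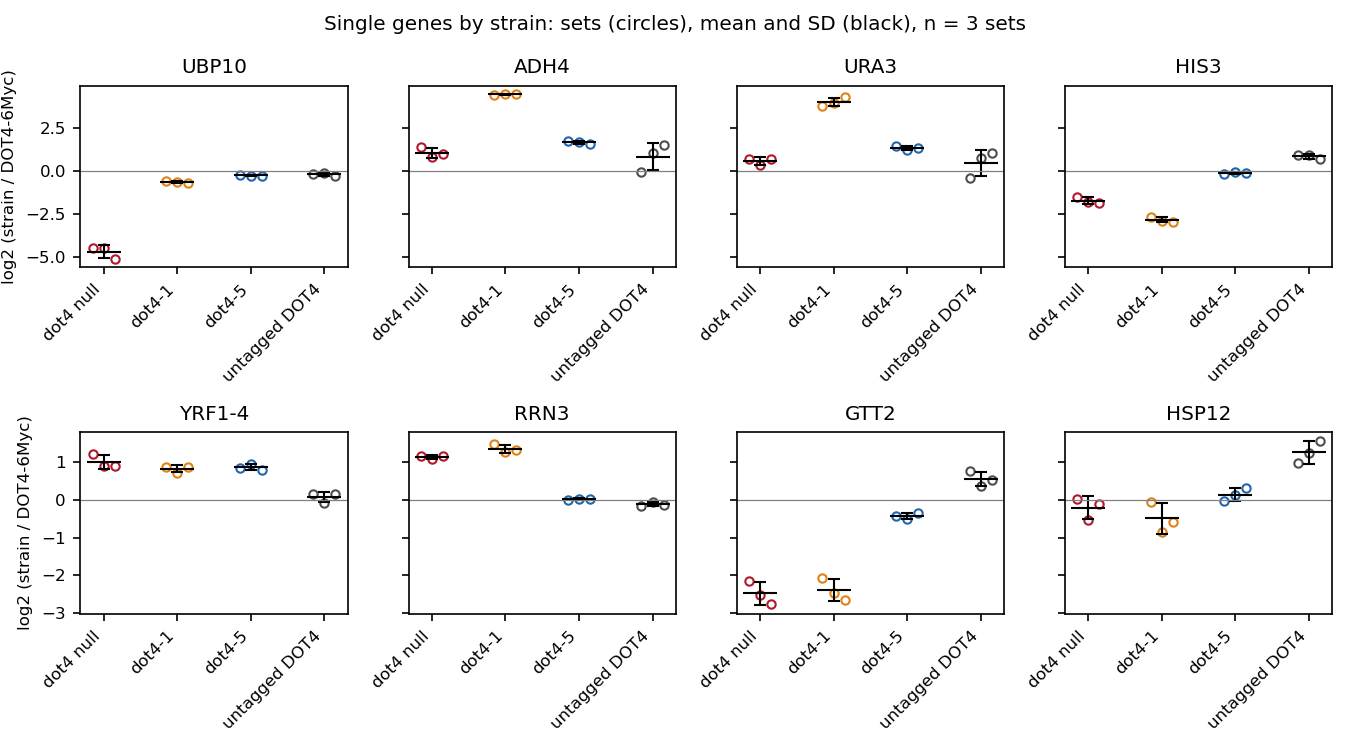
Log2 ratio of each strain to DOT4-6Myc for 8 genes, in the likely direction. Circles are the 3 set means of a strain, and the black line and bars are their mean and SD. UBP10 lies at -4.69 in the strain labelled null, ADH4 and URA3 lie at 4.48 and 4.04 in dot4-1, and the vertical scale differs between the upper and lower panels.

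The comparison of dot4-1 with DOT4-6Myc asks which transcripts differ with that allele. In the likely direction set by UBP10, the largest rises were ADH4 at 4.48 ± 0.014 (22.4-fold, n = 3 sets, adjusted p = 7.85e-09) and URA3 (YEL021W), a uracil synthesis gene and common marker, at 4.04 ± 0.25 (16.5-fold, adjusted p = 1.41e-08). SSA3, a heat-inducible chaperone of the HSP70 family, rose by 1.51 ± 0.14, RRN3 by 1.36 ± 0.11 and the kinase gene FRK1 by 1.24 ± 0.11. DDI2, CHA1, FAL1, BFR2 and DDI3 rose by 1.11 to 1.21. The largest falls were HIS3 at -2.83 ± 0.13 (7.12-fold, adjusted p = 2.31e-10), YNL134C at -2.78 ± 0.36 and YOR203W, which overlaps HIS3, at -2.60 ± 0.12. GTT2 fell to -2.39 ± 0.30 and the cell wall gene SPI1 to -2.06 ± 0.27, followed by GRE2, APE1, YMR173W-A, PGM2 and HSP31 at -1.93 to -1.83. UBP10 itself fell by 0.62 on the log2 scale, with an SD of 0.054 and adjusted p = 7.61e-05.

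In dot4-1, ribosome biogenesis genes rose in 65 of 70 cases and 0 fell (66 adjusted over the list alone, median 0.49), with the helicase gene FAL1 at 1.13 ± 0.077 and UTP9 at 1.02 ± 0.064. Ribosomal protein genes moved the other way: 99 of 138 fell and 20 rose (99 and 21 adjusted over the list alone, median -0.21), with RPS22B at -0.73 ± 0.13, and 66 fell and 11 rose with arrays scaled to a common spread. Stress-induced genes fell in 31 of 37 cases and 2 rose (32 and 2 adjusted over the list alone, median -0.78), with HSP30 at -1.69 ± 0.17 and HSP26 at -1.52 ± 0.37. All 17 glycolysis genes fell (17 adjusted over the list alone, median -0.68), with PGK1 at -1.22 ± 0.18. Oxidative stress genes fell in 18 of 25 cases and 4 rose (19 and 4 adjusted over the list alone), with the glutathione synthesis gene GSH1 at -1.27 ± 0.039. All 7 Y' helicase genes rose (7 adjusted over the list alone, median 0.82), with YRF1-6 at 0.84 ± 0.052, and 21 of 29 PAU genes rose and 7 fell (21 and 7 adjusted over the list alone, median 0.54), with PAU5 at 0.72 ± 0.20. Of 36 genes of silencing and histone modification, 22 rose and 1 fell (22 and 1 adjusted over the list alone, median 0.19), with HST3 at 0.99 ± 0.27 and SIR3 at 0.49 ± 0.16. The camera test gave adjusted p = 3.08e-13 for ribosome biogenesis, 3.58e-06 for ribosomal proteins, 1.03e-08 for the stress genes, 1.93e-06 for glycolysis, 0.000602 for oxidative stress, 0.000181 for the Y' helicases, 0.000602 for the PAU genes and 0.000684 for silencing. For these lists adjusted p = 0.558 to 0.640 with an estimated correlation, so none of these list calls holds with it.

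In dot4-1, 4545 of 6195 genes passed, 2222 higher and 2323 lower, and 96 of them changed by at least 2-fold. URA3, HIS3, TRP1 at -0.97 ± 0.10, LEU2 at -0.94 ± 0.15 and ADE2 at 0.62 ± 0.12 are marker genes, so differences in the marker genotypes stay possible for these 5 genes.

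The comparison of dot4-5 with DOT4-6Myc asks the same of that allele. In the likely direction, ADH4 rose by 1.69 ± 0.10 (3.23-fold, n = 3 sets, adjusted p = 0.000415) and URA3 by 1.35 ± 0.14 (2.55-fold, adjusted p = 0.00264). Next came genes at chromosome ends, YJL225C at 0.89 ± 0.11, YRF1-2 at 0.88 ± 0.088, YRF1-4 at 0.87 ± 0.076, YRF1-1, YBL113C, YEL077C and YIL177C at 0.86, and YML133C at 0.85 ± 0.081. Of the 57 genes that rose, 38 were among the 10 outermost genes of a chromosome end and 13 had no entry in the reference annotation. The place of these 13 was not counted, but some have systematic names between or beside those of outermost genes that rose, such as YEL076W-C, YLR465C and YNL338W. Of the other genes that rose, ADE2 at 0.48, ADE1 at 0.24 and the chaperone gene SSB2 at 0.49 were chosen for mention after their values were seen. URA3 and ADE2 are marker genes, so differences in the marker genotypes stay possible for them. The 7 genes that fell were YOL150C and GRE2 at -0.45, RMD1 at -0.44, YLR108C at -0.37, YDL124W at -0.20, GSH1 at -0.19 and YGR139W at -0.18. UBP10 was at -0.24 ± 0.025 and did not pass (adjusted p = 0.817). It passed at -0.47 with arrays scaled to a common spread and at -0.24 in a fit of dot4-5 alone. Its standard error in the main fit, 0.093, was pooled over the 4 strains, and its SD in the strain labelled null was 0.37.

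In dot4-5, all 7 Y' helicase genes rose (7 adjusted over the list alone, median 0.85, camera adjusted p = 2.17e-51, and adjusted p = 0.0676 with an estimated correlation). Of 11 COS genes, another family near chromosome ends, COS8 at 0.33 ± 0.042 and COS6 at 0.26 ± 0.025 rose (8 adjusted over the list alone, median 0.23, camera adjusted p = 2.01e-12, and adjusted p = 0.558 with an estimated correlation). Among the 29 PAU genes 0 passed (0 adjusted over the list alone), at a median of 0.067, and among the 70 ribosome biogenesis genes 0 passed (0 adjusted over the list alone), the most distant from 0 being at 0.0995 in size. Among 22 heat shock chaperone genes 0 passed (0 adjusted over the list alone), at a median of -0.087 with BTN2 at -0.29 ± 0.22 and HSP42 at -0.23 ± 0.11. The camera test called the PAU genes higher (adjusted p = 9.04e-05) and the chaperones lower (adjusted p = 3.33e-06), and for both lists adjusted p = 0.558 with an estimated correlation. With arrays scaled to a common spread 12 PAU genes rose and 1 fell, 8 COS genes rose and 5 chaperone genes fell, and without centring 1 COS gene rose.

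In dot4-5, 64 of 6195 genes passed with limma, 57 higher and 7 lower, and 269 had an unadjusted p under 0.05. The count was 353 with arrays scaled to a common spread, 187 higher and 166 lower, and 140 in a fit of dot4-5 alone, 90 higher and 50 lower. It was 458 with dot4-5 in Cy5 only, 119 higher and 339 lower, and 437 with it in Cy3 only, 377 higher and 60 lower, so the balance of higher and lower genes turned with the dye. All falls but YLR108C lost their call with a set left out, mostly at values near those with all sets: without set 1 for RMD1 at -0.29, GRE2 at -0.41, YOL150C at -0.43, YDL124W at -0.21, GSH1 at -0.22 and YGR139W at -0.15, without set 3 for the same genes at -0.41, -0.46, -0.48, -0.18, -0.17 and -0.21, and without set 2 for the last 4 at -0.45, -0.21, -0.18 and -0.20. Calls were also lost without centring for YDL124W at -0.19, GSH1 at -0.18 and YGR139W at -0.17, in Cy5 only for RMD1 at -0.28, in Cy3 only for YDL124W at -0.15 and YGR139W at -0.19, with separate arrays for RMD1 and YGR139W, in a fit of dot4-5 alone for RMD1, and with the replicate block for YGR139W.

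The comparison of untagged DOT4 with DOT4-6Myc asks what differs with the tag on the wild-type protein. The largest rises in the likely direction were YGP1 at 1.28 ± 0.18 (2.43-fold, n = 3 sets, adjusted p = 5.12e-05), the hexokinase gene HXK1 at 1.28 ± 0.14 and HSP12 at 1.27 ± 0.30. GPH1, HIS3, YOR203W, APE1, CWP1, YNL134C and STF1 rose by 0.75 to 0.89. HIS3, which YOR203W overlaps, is a marker gene, as is ADE2, which was at -0.61 ± 0.23. Differences in the marker genotypes therefore stay possible for these genes, apart from the tag. The largest falls were the membrane heat shock gene HSP30 at -1.94 ± 0.16 (3.84-fold, adjusted p = 3.23e-08), the kinase gene CMK2 at -1.11 ± 0.16 and MRPL19 (YNL185C), a mitochondrial ribosomal protein gene beside UBP10, at -1.10 ± 0.044. DIA1, MGA1, the zinc transporter ZRT1, SPI1, YOL014W, YOR385W and IZH4 fell to between -1.09 and -0.93. UBP10 was at -0.17 ± 0.081 and did not pass (adjusted p = 0.202), except with scaled arrays at -0.21 and in a fit of untagged DOT4 alone, and SWT21, on its other side, was at -0.10 ± 0.042 (adjusted p = 0.110), passing at -0.18 without centring and at -0.13 with scaled arrays.

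In untagged DOT4, ribosome biogenesis genes fell in 54 of 70 cases and 0 rose (60 adjusted over the list alone, median -0.32), with NSR1 at -0.60 ± 0.11, and 105 of 138 ribosomal protein genes fell and 0 rose (126 adjusted over the list alone, median -0.16). Respiration and TCA cycle genes rose in 24 of 46 cases and 0 fell (30 adjusted over the list alone, median 0.20), with CYT1 at 0.58 ± 0.13 and CIT1 at 0.55 ± 0.083, and 11 rose without centring and 38 with scaled arrays. Stress-induced genes rose in 20 of 37 cases and 4 fell (22 and 5 adjusted over the list alone, median 0.19), HSP30 and SPI1 among the falls. PAU genes fell in 20 of 29 cases and 1 rose (20 and 2 adjusted over the list alone, median -0.30), with PAU20 at -0.37 ± 0.030. The Y' helicases had a median of 0.076 with 0 of 7 past the threshold (0 adjusted over the list alone), and that median changes sign on values without centring. The camera test gave adjusted p = 2.69e-20 for ribosome biogenesis, 1.14e-22 for ribosomal proteins, 1.35e-11 for respiration, 2.81e-05 for the stress genes and 1.75e-09 for the PAU genes. For these lists adjusted p = 0.558 to 0.577 with an estimated correlation, so none of these list calls holds with it.

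In untagged DOT4, 1599 of 6195 genes passed, 692 higher and 907 lower, and 11 of them changed by at least 2-fold. The count was 981 without set 2 and 913 without set 3, and the share of higher genes among those called was 43.3%, against 12.5% on values without centring.

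**Figure D2:**
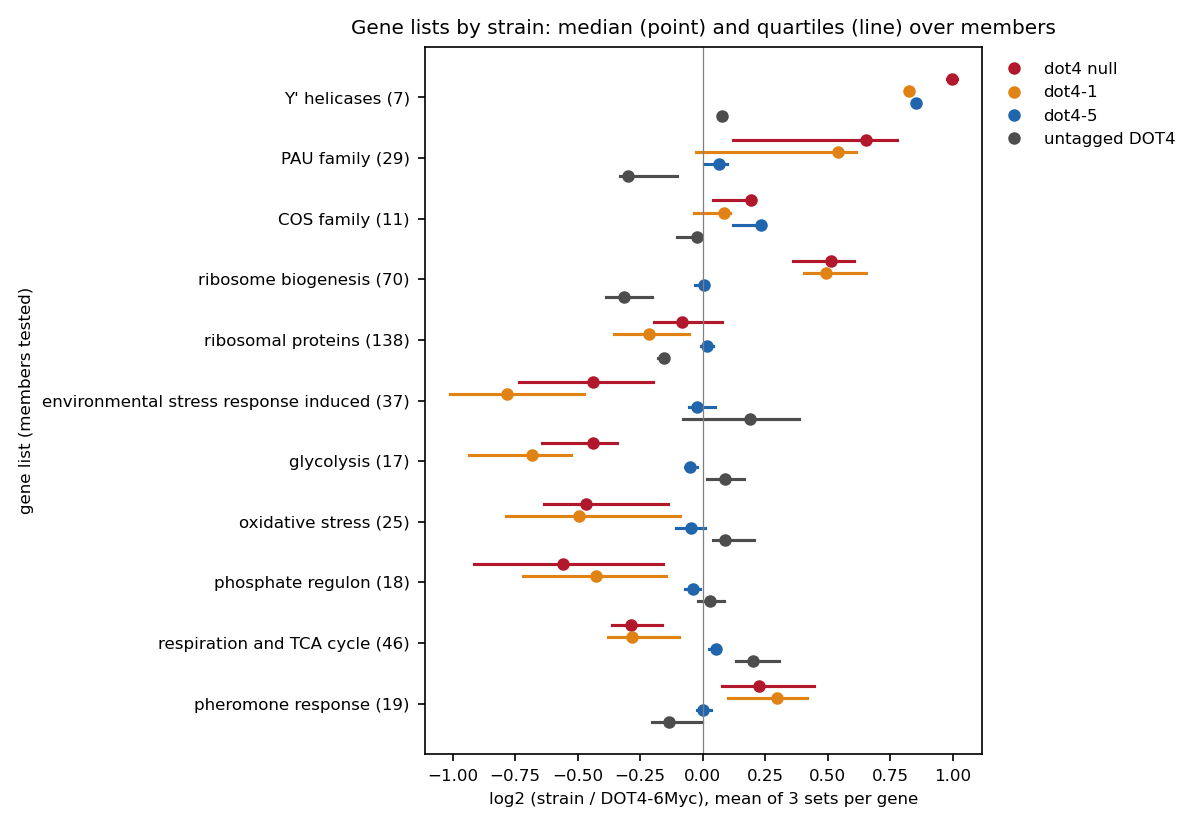
Median (point) and quartiles (line) over the members of 11 gene lists of the log2 ratio of each strain to DOT4-6Myc, in the likely direction. Ribosome biogenesis genes lie at medians of 0.51 in the strain labelled null and 0.49 in dot4-1 and at -0.32 in untagged DOT4, and the Y' helicases lie at 1.00, 0.82 and 0.85 in the strain labelled null, dot4-1 and dot4-5. In untagged DOT4 the medians of the Y' helicases and the phosphate regulon change sign on values without centring.

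The difference between the strain labelled null and untagged DOT4 compares the absence of the gene with its untagged form through the shared reference. In the likely direction, UBP10 was lower in the strain labelled null by a difference of -4.52 (adjusted p = 1.24e-09), from -4.69 ± 0.37 and -0.17 ± 0.081 (n = 3 sets each). HSP30 was higher by 2.21, ZRT1 by 1.89, YOL014W by 1.75, DIA1 by 1.61 and the adenine synthesis gene ADE2 by 1.54. YNL134C was lower at -3.31, GTT2 at -3.04, YGP1 at -2.69 and HIS3 at -2.59. ADE2 and HIS3 are marker genes, so differences in the marker genotypes stay possible for them. All 70 ribosome biogenesis genes were higher (70 adjusted over the list alone, median 0.80), as were all 7 Y' helicases (7 adjusted over the list alone, median 0.91). PAU genes were higher in 22 of 29 cases and lower in 2 (22 and 3 adjusted over the list alone, median 0.98), and respiration and TCA cycle genes were lower in 40 of 46 cases (40 lower and 1 higher adjusted over the list alone, median -0.45). Camera gave adjusted p = 2.78e-22 for ribosome biogenesis, 4.39e-05 for the Y' helicases, 6.01e-08 for the PAU genes and 2.23e-09 for respiration, and for these lists adjusted p = 0.558 to 0.617 with an estimated correlation. Of 6195 genes 3401 passed, 1719 higher and 1682 lower, and the share of higher genes among them was 50.5%, against 69.6% on values without centring. The number of genes would be 2836 if the strain names were exchanged on the null arrays only.

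The difference between dot4-1 and dot4-5 compares the alleles. ADH4 was higher in dot4-1 by 2.79 in the likely direction, from 4.48 ± 0.014 and 1.69 ± 0.10 (n = 3 sets each, adjusted p = 1.20e-05), and URA3 by 2.69 (adjusted p = 1.32e-05). SSA3 was higher by 1.56, RRN3 by 1.33 and FRK1 by 1.27. HIS3 was lower at -2.74, YOR203W at -2.53, YNL134C at -2.35, GTT2 at -1.96 and PGM2 at -1.93. UBP10 was lower at -0.38 (adjusted p = 0.0257), and arrays scaled to a common spread turn the sign of UBP10 to 0.10, of ADH4 to -0.69 and of URA3 to -0.27. The call of UBP10 was also lost without dot4-1 set 2 at -0.39 and set 3 at -0.35, and without dot4-5 sets 1, 2 and 3, at -0.36, -0.38 and -0.39, with adjusted p = 0.0526 to 0.0757 over these, and in Cy5 alone at -0.35, in Cy3 alone at -0.41 and with separate arrays. Ribosome biogenesis genes were higher in 64 of 70 cases and 0 were lower (64 and 1 adjusted over the list alone, median 0.50). All 17 glycolysis genes were lower (17 adjusted over the list alone, median -0.66), and stress-induced genes were lower in 29 of 37 cases and higher in 2 (30 and 2 adjusted over the list alone, median -0.75). The camera test gave adjusted p = 7.99e-14 for ribosome biogenesis, 1.83e-06 for glycolysis and 4.12e-09 for the stress genes, and for these lists adjusted p = 0.558 to 0.562 with an estimated correlation. Among the 7 Y' helicases 0 passed (0 adjusted over the list alone), at a median of -0.035, whereas with arrays scaled to a common spread, which enlarges the values of dot4-5, all 7 were lower at a median of -1.18. Under the same scaling 10 glycolysis genes were lower. Of 6195 genes 3779 passed, 1836 higher and 1943 lower, and 2246 with arrays scaled to a common spread.

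The difference between the strain labelled null and dot4-1 compares the absence of the gene with that allele. UBP10 was lower in the strain labelled null, in the likely direction, at -4.07 (adjusted p = 4.27e-09), from -4.69 ± 0.37 and -0.62 ± 0.054 (n = 3 sets each), URA3 at -3.44 and ADH4 at -3.42. GAL11, at -1.28, and YGR242W, at -0.76, were lower with values in 2 sets of the strain labelled null, and YGR242W lost its call without null set 2, at -0.66, with scaled arrays, at -0.55, and in either dye orientation alone, at -0.65 and -0.71. GAL11 lost its call with the compared strains in Cy3 only, at -0.57, and MGA1 with scaled arrays, at 0.77. YGR242W, GAL11 and MGA1 all lost it in a fit of these 2 strains without the set number as a replicate block, and kept it with that block. HSP30 was higher by 1.96, from 0.27 ± 0.16 and -1.69 ± 0.17, SPI1 by 1.79, FMP48 by 1.45, MGA1 by 1.29 and URA1 by 1.25. Stress-induced genes were higher in 14 of 37 cases and lower in 3 (18 and 3 adjusted over the list alone, median 0.30), and ribosomal protein genes in 24 of 138 cases and lower in 0 (48 and 0 adjusted over the list alone, median 0.13). Of 10 histone genes 5 were higher (6 adjusted over the list alone, median 0.22), with HTA1 at 0.50 and HTA2 at 0.49. These counts depended on the scaling: without centring 13 stress genes, 1 ribosomal protein gene and 3 histone genes were higher, and with scaled arrays 2, 0 and 0. The camera test gave adjusted p = 2.20e-07 for the stress genes, 3.25e-13 for ribosomal proteins and 0.000434 for histones, and for these lists adjusted p = 0.558 with an estimated correlation. Of 6195 genes 608 passed, 309 higher and 299 lower. The same-numbered sets of these strains moved together, and with the set number as a replicate block the count was 656, or 866 in a fit of these 2 strains with the block, an alternative chosen after seeing the data. It was 242 without centring, 37 with scaled arrays, 339 with the compared strain in Cy5, 101 in a fit of these 2 strains without the block, and 373, 1132, 267 and 349 without null set 2, null set 3, dot4-1 set 2 and dot4-1 set 3. If the strain names were exchanged on the null arrays only, which these values do not exclude, 4835 genes would differ.

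The difference between the strain labelled null and dot4-5 compares the absence of the gene with that allele. In the likely direction, UBP10 was lower in the strain labelled null at -4.45 (adjusted p = 1.47e-09), from -4.69 ± 0.37 and -0.24 ± 0.025 (n = 3 sets each). YNL134C was lower at -2.12, GTT2 at -2.05, PHO89 at -1.92 and GAL11, with 2 sets, at -1.89. BPH1 was higher by 1.20, RRN3 by 1.12, CHA1 by 1.08, TDA6 by 1.05 and the inositol synthesis gene INO1 by 1.03. Ribosome biogenesis genes were higher in 66 of 70 cases and 0 were lower (66 adjusted over the list alone, median 0.50), and PAU genes were higher in 21 of 29 cases and lower in 3 (21 and 5 adjusted over the list alone, median 0.58). For ribosome biogenesis camera gave adjusted p = 1.93e-18 and for the PAU genes 4.79e-07, and for both adjusted p = 0.558 with an estimated correlation. Among the 7 Y' helicases 0 passed (0 adjusted over the list alone), at a median of 0.14 that turns to -0.96, with all 7 lower, with arrays scaled to a common spread. Of 6195 genes 2941 passed, 1442 higher and 1499 lower, and 1920 with scaled arrays. The count would be 3002 with strain names exchanged on the null arrays only.

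Genes near chromosome ends were counted in each strain against DOT4-6Myc. Of the 294 genes among the 10 outermost of an end, 38 rose in dot4-5 in the likely direction, against 5 of 5386 other genes (odds ratio 159, 95% interval 61.9 to 515, Fisher's exact test, p = 9.67e-45). With arrays scaled to a common spread 74 of the 294 rose in dot4-5 and 14 fell, against 38 and 0, and no odds ratio was computed on those values. In the strain labelled null 126 of these 294 genes rose, against 1670 of the others (odds ratio 1.67, Fisher's exact test, p = 3.48e-05), and in dot4-1 135 rose against 1968 (odds ratio 1.47, Fisher's exact test, p = 0.00152). In untagged DOT4 26 rose against 643 (odds ratio 0.716, Fisher's exact test, p = 0.115). By rank, 42 of the 55 genes at ranks 1 to 2 rose in the strain labelled null (median 0.67), 37 in dot4-1 (median 0.54), 25 in dot4-5 (median 0.24) and 1 in untagged DOT4. With the 5 outermost genes of each end, Fisher's exact test gave odds ratios of 321 in dot4-5 (p = 2.53e-55), 3.18 in the strain labelled null (p = 1.52e-11), 2.48 in dot4-1 (p = 1.44e-07) and 0.557 in untagged DOT4 (p = 0.0861). The excess in dot4-1 and in the strain labelled null did not pass with 20 genes per end, without the family lists, or without the 2 outermost genes. The odds ratios were 1.05, 1.24 and 1.21 in dot4-1 and 1.17, 1.25 and 1.21 in the strain labelled null. In dot4-5 they were 89.5, 139 and 61.7. The family lists were the Y' helicases, PAU, COS, hexose transporter, flocculation and thiamine genes. The Y' helicase list held only the 7 YRF1 genes. Genes such as YJL225C and YBL113C, with ratios like theirs in dot4-5, stayed in, and 28 of 242 genes rose there. The excess in dot4-5 was therefore not tested without all near-identical genes. Probes of near-identical families such as the YRF1 genes can share signal, so their members are not independent.

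**Figure D3:**
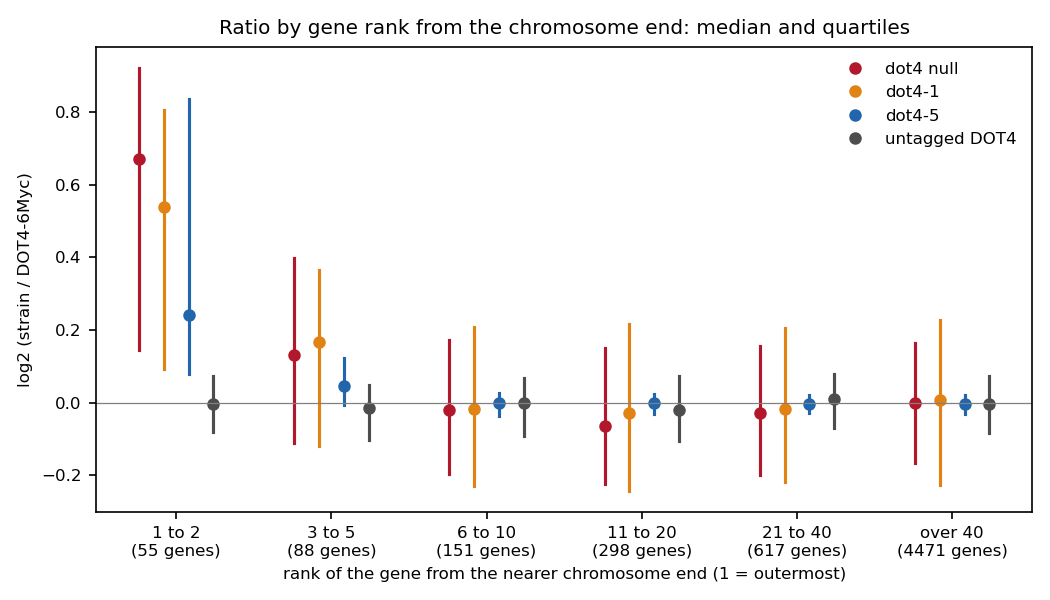
Median (point) and quartiles (line) of the log2 ratio of each strain to DOT4-6Myc, in the likely direction, by the rank of the gene from the nearer chromosome end. At ranks 1 to 2 the medians are 0.67 in the strain labelled null, 0.54 in dot4-1 and 0.24 in dot4-5, and at ranks 6 to 10 they are -0.020, -0.018 and -0.00033.

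Across 6176 genes, the profiles of dot4-1 and the strain labelled null correlated at Pearson r = 0.86, among the genes RRN3, HIS3, YNL134C and GTT2 far from 0 in both. Simulated noise gave r = 0.494, with a covariance of 0.00197 against the measured 0.103. That simulation assumed that the shared reference makes up 0.50 of each gene's variance between sets. Its r follows from this setting and is not a measured baseline. Between sets with different numbers the measured r was 0.782 to 0.814. Of the 2222 genes higher in dot4-1, 1632 were also higher in the strain labelled null, where 683 would be under independence, a value that makes no allowance for the shared reference. Of the 2323 lower in dot4-1, 1704 were also lower there, where 759 would be. The profile of dot4-5 correlated at 0.27 with dot4-1 and at 0.29 with the strain labelled null, and the Spearman correlations were 0.089 and 0.12. Both Pearson values were under the 0.50 that followed from the assumed share in simulation. Those simulated profiles hold noise alone, and the covariances, at 0.00898 and 0.00813, were over the simulated 0.00200 and 0.00201, with r of 0.241 to 0.280 and 0.180 to 0.298 between sets with different numbers, so whether most genes share a response stays open. The profile of untagged DOT4 correlated at -0.33 with the strain labelled null, where the simulation with the assumed share gave 0.50. Of the 57 genes higher in dot4-5, such as ADH4 and the YRF1 genes, 53 were higher in dot4-1 and 55 in the strain labelled null. Under independence these would be 20.4 and 17.5, again with no allowance for the shared reference, and many of the 57 belong to near-identical families at chromosome ends and are not separate cases. If the strain names were exchanged on the null arrays only, r of 0.86 would change its sign and the 1632 and 1704 genes would have moved in opposite directions in dot4-1 and the strain labelled null. The 55 genes would then have moved in opposite directions in dot4-5 and that strain, and its r of 0.29 and -0.33 would also change sign. These correlations are across genes, which are not independent replicates.

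**Figure D4:**
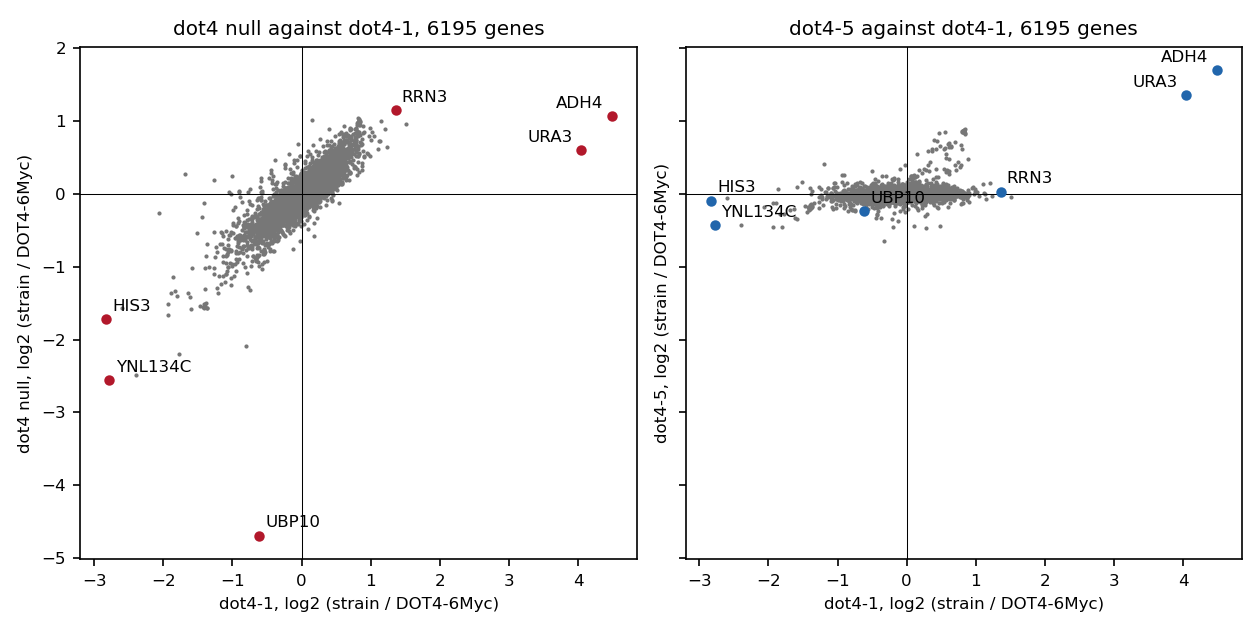
Mean log2 ratio to DOT4-6Myc of the strain labelled null (left) and of dot4-5 (right) against dot4-1, each point 1 of 6195 genes, in the likely direction. On the left r = 0.86 across 6176 genes, and UBP10, ADH4 and URA3 lie farthest from the diagonal, with others such as HSP30, at 0.27 against -1.69, also away from it. On the right ADH4 and URA3 rise in both strains, and RRN3 and HIS3 lie at 1.36 and -2.83 in dot4-1 and at 0.026 and -0.097 in dot4-5.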

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

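The tests of explanations in this part were all chosen after the results were seen. The differences below were tested as differences of strains in 1 fit, and each value passed that test.

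Between the strain labelled null and untagged DOT4, 3401 genes and 14 gene lists differed, with UBP10 at -4.52, SWT21 at 0.49, MRPL19 at 1.31, HSP30 at 2.21, ZRT1 at 1.89, YOL014W at 1.75, DIA1 at 1.61, ADE2 at 1.54, YNL134C at -3.31, GTT2 at -3.04, YGP1 at -2.69 and HIS3 at -2.59. Between dot4-1 and dot4-5, 3779 genes and 13 lists differed, with UBP10 at -0.38, SWT21 at 0.26, MRPL19 at 0.54, ADH4 at 2.79, URA3 at 2.69, SSA3 at 1.56, RRN3 at 1.33, FRK1 at 1.27, HIS3 at -2.74, YOR203W at -2.53, YNL134C at -2.35, GTT2 at -1.96 and PGM2 at -1.93. Between the strain labelled null and dot4-1, 608 genes and 11 lists differed, with UBP10 at -4.07, MRPL19 at -0.38, HSP30 at 1.96, SPI1 at 1.79, FMP48 at 1.45, MGA1 at 1.29, URA1 at 1.25, URA3 at -3.44, ADH4 at -3.42, GAL11 at -1.28 and YGR242W at -0.76. Between the strain labelled null and dot4-5, 2941 genes and 13 lists differed, with UBP10 at -4.45, SWT21 at 0.42, BPH1 at 1.20, RRN3 at 1.12, CHA1 at 1.08, TDA6 at 1.05, INO1 at 1.03, YNL134C at -2.12, GTT2 at -2.05, PHO89 at -1.92 and GAL11 at -1.89. Between the strain labelled null and dot4-1, MRPL19 lost its call without null set 2 at -0.32, with scaled arrays at -0.21 and with the compared strain in Cy5 only at -0.28, and YGR242W without null set 2 at -0.66, with scaled arrays at -0.55, in Cy5 only at -0.65 and in Cy3 only at -0.71. MGA1 lost its call there with scaled arrays at 0.77 and GAL11 in Cy3 only at -0.57. A fit of these 2 strains without the replicate block called none of these 4 genes, while the same fit with the block called all 4. SWT21 lost its call in Cy3 only, at 0.24 between the strain labelled null and dot4-5 and at 0.17 between dot4-1 and dot4-5. UBP10 between dot4-1 and dot4-5 lost its call in Cy5 only at -0.35, in Cy3 only at -0.41, with separate arrays, with scaled arrays, where its sign turned to 0.10, and without dot4-1 set 2, at -0.39, and set 3, at -0.35, and without dot4-5 sets 1, 2 and 3, at -0.36, -0.38 and -0.39. The list counts are those of camera with a preset correlation, and 0 of them hold with an estimated one.

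With 3 sets, turning the signs of sets gives 4 arrangements and splitting 6 sets into groups of 3 gives 10, so that no share under 0.05 can be reached. In every comparison 1 arrangement or split, the real one, gave as many genes. Where sets agree, turning or regrouping them moves their shared ratio into the spread. Low counts in the other arrangements then follow from that agreement and say nothing about its cause. The real counts were 4545 for dot4-1, 64 for dot4-5, 3928 for the strain labelled null and 1599 for untagged DOT4, against highest others of 0, 0, 1 and 0. For the differences they were 3401 for the strain labelled null against untagged DOT4, 3779 for dot4-1 against dot4-5, 608 for the strain labelled null against dot4-1 and 2941 for it against dot4-5, against highest others of 1, 0, 0 and 0.

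UBP10 was higher in the strain labelled null in the order of the labels, Cy5 over Cy3. An inversion on the null arrays only would turn their dye component against that of the other strains, and the lowest correlation with another strain was 0.822, which argues against it. An inversion on all arrays needs UBP10 higher in both dye orientations. That held on 6 of 6 null arrays but is the pattern itself, so it is no separate test. Such an inversion may account for the pattern. Strain names exchanged on the null arrays only cannot be told apart from it, because the dot4-1 and null profiles, which correlated at 0.86 as turned here, would then run against each other, and no value in these tables excludes that for an allele and a deletion. The count between the strain labelled null and dot4-1 would then be 4835 in place of 608.

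URA3 and ADH4 rose together in dot4-1, in dot4-5 and, by 0.60 and 1.07, in the strain labelled null, while in untagged DOT4 ADH4 passed at 0.84 ± 0.80 with 1 of 3 sets at -0.03, and URA3, at 0.49 ± 0.76, did not. A change that spreads from the native place of URA3 would raise the genes beside it, and the largest rise among its 4 nearest measured neighbours in dot4-1 was 0.23, at TIM9, against 4.04 at URA3. A rise of the genes beside ADH4 by as much as ADH4 was not seen either, where the largest of 4 was 0.80, at ZRT1, against 4.48. URA3 minus ADH4 was -0.44, -0.34, -0.47 and -0.35 in dot4-1, dot4-5, the strain labelled null and untagged DOT4, a range of 0.12, which is consistent with URA3 placed beside ADH4 as a reporter, a hypothesis that the labels do not settle. An effect of DOT4 on that place stays open and was not tested.

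Ribosome biogenesis genes rose and stress genes fell in dot4-1 and in the strain labelled null. Faster growth as the whole cause would raise ribosomal protein genes too, and their median was -0.21 in dot4-1 with an upper quartile under 0, which argues against it there, while in the strain labelled null their upper quartile of 0.078, under the lower quartile of 0.36 of the ribosome biogenesis genes, argues against a rise as large, and their median of -0.082, with members on both sides of 0, leaves a smaller one open. Reference RNA shared by sets of the same number does not account for the pattern in dot4-1 and the strain labelled null, since the lowest correlation between sets with different numbers was 0.782. A state of the reference common to every array would show in dot4-5, where the ribosome biogenesis gene farthest from 0 had 0.0995, though another batch of reference RNA on the dot4-5 arrays stays possible. An effect of DOT4 itself, or of other differences between the strains, stays open and could not be separated here.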

How the results depend on the processing

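Of 1924 values of named genes under the alternatives, 1862 were counted as unchanged, 52 lost their call, 7 gained one and 3 that had passed changed sign. A change of sign in a value that had not passed was counted as unchanged. The alternatives added after seeing the data were the deposited direction, the fit of 2 strains with the replicate block, genes 3 to 10 of each end, and strain names exchanged on the null arrays only. The deposited direction puts UBP10 at 4.69 in the strain labelled null. With strain names exchanged on its arrays only, that strain would differ from untagged DOT4 in 2836 genes, from dot4-1 in 4835 and from dot4-5 in 3002. Scaling arrays to a common spread puts the difference of dot4-1 and dot4-5 at 0.10 for UBP10, -0.69 for ADH4 and -0.27 for URA3, because it enlarges the narrow arrays of dot4-5 by construction. The same scaling gave 353 genes in dot4-5 (64 without it), 2246 between dot4-1 and dot4-5, 37 between the strain labelled null and dot4-1, and 1920 between it and dot4-5.

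For dot4-5 the count was also 458 with the strain in Cy5 only, 437 in Cy3 only, where a dye effect no longer cancels, and 140 in a fit of that strain alone. For the strain labelled null against dot4-1 it was 242 as deposited, 339 in Cy5 only, 101 in a fit of the strains compared, and 656 and 866 with the replicate block, against 608. Leaving out each set gave 913 to 1088 for untagged DOT4, against 1599, and 267 to 1132 for the strain labelled null against dot4-1. For the other 6 comparisons the counts without each set stayed within 1.5 times. The share of higher genes in dot4-5 moved from 89.1% to 53.0% with scaled arrays. Leaving out the centring moved the median of all genes most between the strain labelled null and untagged DOT4, from -0.0034 to 0.095.

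Of 280 list tests, camera called 106, and 0 with an estimated correlation, 144 with fry, 219 with fry in either direction, 109 with the replicate block and 111 as deposited. The medians of genes near chromosome ends, 0.10 in dot4-1, 0.022 in dot4-5 and 0.051 in the strain labelled null, also lost their call with an estimated correlation. In Fisher's exact tests the odds ratio near chromosome ends lost its call at 1.05 in dot4-1 and 1.17 in the strain labelled null with 20 genes per end. It was also lost at 1.24 and 1.25 without the family lists, and at 1.21 and 1.21 for genes 3 to 10. Spearman correlations were 0.089 for dot4-1 with dot4-5 and 0.12 for dot4-5 with the strain labelled null. Where no cause is named, the cause was not tested. Signal over background is not given in the sources used here, so its effect on weak transcripts was not measured.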

Other observations

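In the likely direction, histone genes moved apart by type in dot4-1. There the H4 genes HHF1 and HHF2 rose by 0.60 ± 0.010 and 0.62 ± 0.0013 (SD, n = 3 sets) and the H3 genes HHT1 and HHT2 by 0.35 and 0.23, while the H2A genes HTA1 and HTA2 fell to -0.59 each and the H2B genes HTB1 and HTB2 to -0.45 each. In the strain labelled null HHF1 and HHF2 rose by 0.62 and 0.60 and HHT1 and HHT2 by 0.39 each, HTB1 and HTB2 fell to -0.14 and -0.15, and HTA1 and HTA2, at -0.092 and -0.093, did not pass. The falls in the strain labelled null were lost with the scaling: 3 of 10 histone genes fell there (4 adjusted over the list alone), against 0 without centring and 0 with arrays scaled to a common spread. In untagged DOT4 HTB1 and HTB2 rose by 0.35 each, and in dot4-5 0 of the 10 histone genes passed (0 adjusted over the list alone). These genes were grouped by type after their values were seen. Both genes of a type mostly had near-equal values, and whether their probes share signal was not tested, so they may not be separate cases.

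Genes of the pheromone response rose in 12 of 19 cases in the strain labelled null and 1 fell (12 and 1 adjusted over the list alone, median 0.23), with SST2 at 0.76 ± 0.12 and PRM1 at 0.72 ± 0.17 (camera adjusted p = 0.00595, and adjusted p = 0.558 with an estimated correlation). In dot4-1 they rose in 12 of 19 cases and 2 fell (13 and 2 adjusted over the list alone, median 0.30), with SST2 at 0.71 ± 0.17 and CIK1 at 0.65 ± 0.13 (camera adjusted p = 0.0162, and adjusted p = 0.577 with an estimated correlation). The 6 silent mating loci and mating-type genes were not called as a list by camera in dot4-1 (adjusted p = 0.359), in the strain labelled null (adjusted p = 0.491) or in untagged DOT4 (adjusted p = 0.0886). Of single members, HMRA1 rose by 0.39 ± 0.032 in dot4-1 and 0.35 ± 0.042 in the strain labelled null, HMRA2 by 0.27 and 0.18 and also by 0.15 in untagged DOT4, HMLALPHA2 rose by 0.15 in untagged DOT4, and MATALPHA1 fell to -0.19 in the strain labelled null. With scaled arrays 1 member rose and 0 fell in the strain labelled null, and without centring 0 rose in untagged DOT4.

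MRPL19, beside UBP10, rose by 0.59 ± 0.15 in dot4-1 and by 0.22 ± 0.16 in the strain labelled null, and fell to -1.10 ± 0.044 in untagged DOT4. The call in the strain labelled null was lost without its set 1, at 0.13, and with that strain in Cy3 only, also at 0.13. SWT21, on the other side, rose by 0.24 ± 0.026 in dot4-1, which did not pass at 0.14 with that strain in Cy3 only, and by 0.39 ± 0.12 in the strain labelled null. GAL11, a subunit of the Mediator complex, was at -2.09 in the strain labelled null with values in 2 sets, at -0.81 in dot4-1 and at -0.21 in dot4-5, where it did not pass.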
